A study of Arabidopsis thaliana with 5 samples.

How the data were processed

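RNA-seq libraries were made from total RNA of Arabidopsis thaliana roots, with 3 libraries of the wild type Col-0 and 2 of the genotype GFP-GrxS5; groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA came from roots and shoots by column extraction, while all 5 libraries are labelled as root. Also per the labels' protocols, 1 µg went into each library preparation, and the libraries were made with a TruSeq kit and sequenced on a MiniSeq or made with an NEBNext Ultra II kit and sequenced on a NextSeq550. Which library had which is not given in the sources used here. Per the submitters' processing notes the genome build was TAIR10. The aligner, the quantification program and their versions are not given in the sources used here. The values analysed are FPKM per gene as deposited by the authors, which per the file headers come with a lower and an upper bound and a status for each of 33557 features, in 1 file per library. The lower bound equals the FPKM in all rows of status OK, so the bounds were not used. FPKM divides fragments by gene length and by the library's total; which fragments the total counts, how reads shared by similar genes were split and whether strand was used are not given in the sources used here. Genes with near-identical copies, overlapping genes and the 3249 tested genes listed under a locus shared with another gene are therefore uncertain; among the named genes the latter holds for MYB72, F6'H1, CLCa, AMT1;1, G6PD3, APR2, YSL2, TGA4, CHS and BCAT4.

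Depth was estimated from the FPKM values. Genes with 1 annotated transcript of 1500 to 4000 bp and low FPKM cluster at the value of 1 fragment, and the mode of FPKM times length, taken as 1 fragment, gave 4390000, 3850000, 4160000, 4260000 and 3400000 fragments for Col-0 replicates 1 to 3 and GFP-GrxS5 replicates 1 and 2. The steps were too blurred to recover whole counts, so no count model was fitted, and on 1.5 kb 1 fragment is worth 0.152 to 0.196 FPKM. Lengths and GC content came from the TAIR10.1 annotation, matched by gene identifier for 32805 features; printed coordinates are those of the files, on TAIR10, counted from 1. Across tested genes, Pearson correlations of log2(FPKM + 1) were 0.975 to 0.979 between libraries of a genotype and 0.960 to 0.965 between genotypes (genes are not independent replicates), and the first principal component held 46.8% of the variance and separated the genotypes.

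Genes with FPKM of at least 1 in at least 2 of the 5 libraries and status OK in every library were kept, 19693 in all; TPL and AT1G15740 were left out because their status was FAIL in Col-0 replicate 1 and GFP-GrxS5 replicate 2. GFP-GrxS5 was compared with Col-0 on log2(FPKM + 1), with no further scaling, by a linear model with moderated variances that follow a trend on expression (limma 3.58.1 in R 4.3.3, two-sided), and p-values were adjusted by Benjamini-Hochberg over the kept genes with a threshold of 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and errors of FPKM are SD over the libraries of a group. The model had 3 residual and a median of 4.37 prior degrees of freedom. Gene lists (27 lists, 435 genes, of which 434 had values) were tested with limma's camera at a preset inter-gene correlation of 0.01 and with the same variance trend, adjusted by Benjamini-Hochberg over the lists. Of them 11 passed, 0 with an estimated correlation and 6 with fry, which tests whether a list's genes move on balance one way and does not compare them with other genes. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, except that the use of the variance trend in camera was settled after its results with and without the trend had been seen.

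The rule named GrxS1 to GrxS8, the 10 largest rises and 10 largest falls among genes past the threshold whose GFP-GrxS5 libraries both lay on the same side of all Col-0 libraries, at most 4 members of each list with the smallest p, and NRT2.1, CEPH, TGA1 and TGA4. Named outside the rule after their values were seen were IRT1, FIT, NAS1, F6'H1, S8H, NRAMP1, ZIF1, ZIP2, NRT1.1, NRT3.1, NIA2, ASN1, GDH2, CHS, BCAT4, CYP83A1, DRM1, DRM2, MCM2, PLT1 and, in the closing section, EXL2, GLK2, HY5 and leaf transcripts. List names are used for genes that the files call otherwise, such as NPF7.3 for NRT1.5, NPF6.3 for NRT1.1, GRXS11 for CEPD1, ORG2 for bHLH38, ABCG37 for PDR9, ERF094 for ORA59, ERF073 for HRE1, MED37C for HSP70-4, DFRA for DFR, CHI3 for CHIL, A3 for EF1A, BCA1 for CA1 and DYL1 for DRM1. A further 4 lists (leaf markers outside photosynthesis, aliphatic glucosinolate synthesis, carbon starvation and dormancy, chloroplast development regulators) were written after the main results were seen.

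Alternatives were pseudocounts of 0.1 and 0.5, no filter or a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, nuclear genes rescaled to equal sums, moderation without a trend or robust, array weights, all rows whatever their status, the replicate number as a block, leaving out each library in turn, and, for lists, an estimated correlation and fry. Removal of features under 300 bp and a loess correction for GC content and length (span 0.5) were added after seeing the data. Where GFP-GrxS5 keeps 1 library, that library is assumed to vary as the Col-0 libraries do. The scripts were tested on simulated data for this comparison, with 19683 genes kept and 200 changed by known folds. The iron deficiency genes were lowered 2-fold as a set. Counts were drawn at the estimated depths, independently for each gene and with the same assumed dispersion for all genes. Of the 200 genes the fit recovered 22.4% of 1.5-fold, 77.6% of 2-fold and 95.5% of 4-fold changes. Of all 167 calls, those on the iron deficiency genes included, 11 were false (6.6%). Figures and tables used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.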

Results

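RNA was profiled in roots of Arabidopsis thaliana from the wild type Col-0 (3 libraries) and from plants labelled GFP-GrxS5 (2 libraries). GrxS5 is a plant-specific glutaredoxin, a small redox protein of a class that includes partners of TGA transcription factors. The label names green fluorescent protein joined to GrxS5, and the construct and its promoter are not described in the labels. The comparison asks which genes GrxS5 represses. Each library has an FPKM value for 33557 features. Fragment steps in the low FPKM values put the depth near 4390000, 3850000 and 4160000 fragments for Col-0 replicates 1 to 3. It was near 4260000 and 3400000 fragments for GFP-GrxS5 replicates 1 and 2. A gene of 1.5 kb at 1 FPKM then rests on 5.1 to 6.6 fragments.

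GrxS5 itself (protein-coding gene AT4G15690; chromosome 4, 8934324 to 8934921) stood at 3.48 ± 0.582 FPKM (SD, n = 3) in Col-0 and at 114 ± 14.8 FPKM (SD, n = 2) in GFP-GrxS5 roots, a rise of 4.68 on the log2 scale (SE 0.15; limma, Benjamini-Hochberg adjusted p = 2.84e-05). With it the root iron transporter gene IRT1 fell from 264 ± 15.3 to 78.4 ± 28.1 FPKM, the ferric reductase gene FRO2 from 141 ± 11.4 to 32.1 ± 10.9 and the copper transporter gene COPT2 from 47 ± 3.5 to 9.66 ± 3.19. NRT1.5, which loads nitrate into the xylem, fell from 306 ± 30.6 to 122 ± 12.4 FPKM, and NIA1, a nitrate reductase gene, from 349.9 ± 42.3 to 180.4 ± 17.1. In the opposite direction, the Rubisco small subunit gene RBCS1A rose from 160.1 ± 10.8 to 374 ± 16.8 FPKM and the light-harvesting gene LHCB1.3 from 198 ± 31 to 531 ± 21.1 (SD throughout, n = 3 and n = 2; limma, Benjamini-Hochberg adjusted p between 6.15e-04 and 0.00422 for these 7 genes). Reads of the fusion transcript and of the native GrxS5 gene are not separated in these values.

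**Figure D1:**
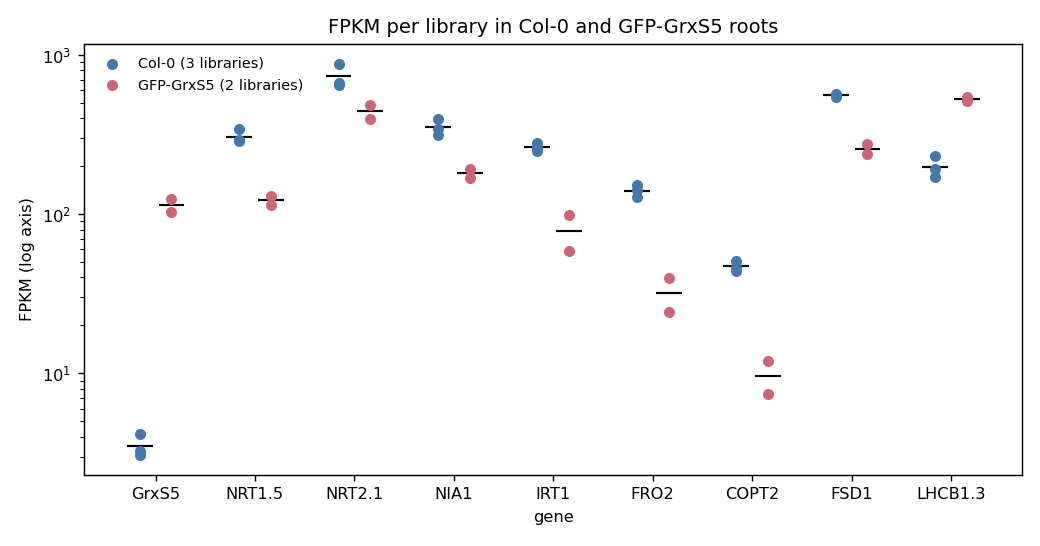
FPKM of 9 genes (log axis) in each Col-0 library (blue, n = 3) and each GFP-GrxS5 library (red, n = 2), with group means as black lines. GrxS5 and LHCB1.3 lie above the Col-0 values in both GFP-GrxS5 libraries, and the other 7 genes lie below them.

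Of 19693 genes tested, 932 were higher and 462 lower in GFP-GrxS5 roots at a limma Benjamini-Hochberg adjusted p under 0.05. Of these, 230 higher and 103 lower genes changed at least 2-fold. In each of the 1394 called genes both GFP-GrxS5 libraries lay on the same side of all Col-0 libraries, which held for 42.8% of all tested genes against 20% by chance. The higher genes were 66.9% of the calls. Quantile normalization gave 789 higher and 648 lower genes (54.9% higher). A GC and length correction, chosen after seeing the data, gave 756 and 597 (55.9% higher). Without Col-0 replicates 1, 2 and 3 in turn, 535, 594 and 579 genes were higher and 232, 227 and 242 lower. Without GFP-GrxS5 replicates 1 and 2 in turn, 313 and 365 were higher (125 and 148 at least 2-fold) and 208 and 192 lower. With limma's variances moderated without a trend on expression, 398 were higher and 184 lower. The labels name 2 library kits and 2 sequencers without saying which library had which, so a technical batch and the genotype cannot be told apart here. The labels do not say that replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical.

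**Figure D2:**
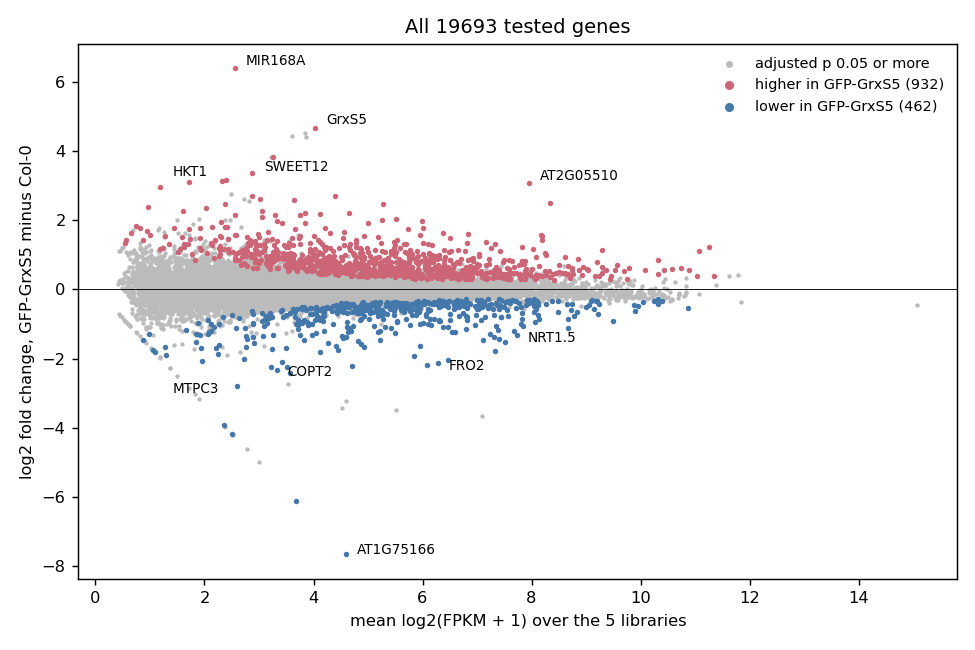
Log2 fold change (GFP-GrxS5 minus Col-0, of FPKM + 1) of each of the 19693 tested genes against its mean log2(FPKM + 1) over the 5 libraries. Red points mark the 932 higher and blue points the 462 lower genes past the adjusted p threshold, and grey points the rest. Features listed at 0 in a whole group are placed by the added 1 FPKM, so their position is no fold change.

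SWEET12 and HKT1 were among the largest rises. SWEET12, a sucrose exporter, rose from 1.89 ± 0.429 to 28.9 ± 0.915 FPKM and HKT1, a sodium transporter, from 1.2 ± 0.127 to 18.8 ± 2.45 (SD, n = 3 and n = 2; limma, Benjamini-Hochberg adjusted p = 3.41e-04 and 3.41e-04). The neighbouring glycine-rich protein genes AT2G05510 and GRP3 rose from 106 ± 16 to 886 ± 9.63 and from 1.14 ± 0.566 to 17.7 ± 3.3 FPKM, and AT1G15125 rose from 0.441 ± 0.414 to 11.1 ± 2.43. LDOX, of anthocyanin synthesis, rose from 2.76 ± 1.69 to 21.7 ± 3.17 FPKM. Its call was lost without either 1 of the GFP-GrxS5 replicates (limma, Benjamini-Hochberg adjusted p from 0.0552 to 0.0724, and 0.00326 to 0.0724 over all alternatives). Among the largest falls, the cation efflux gene MTPC3 went from 12.2 ± 1.0 to 0.918 ± 0.166 FPKM and AT4G01390 from 23 ± 6.58 to 3.34 ± 0.135. FRO5, a metal reductase gene near-identical to its neighbour FRO4, fell from 20.4 ± 1.04 to 3.51 ± 0.17 FPKM. AT5G38820 fell from 16.7 ± 3.77 to 3.23 ± 2.94 FPKM, a call lost without Col-0 replicates 1 or 3 (limma, Benjamini-Hochberg adjusted p from 0.0681 to 0.0728, and 0.0054 to 0.075 over all alternatives). Its log2 change was -2.24, against -3.02 and -1.47 without GFP-GrxS5 replicates 1 and 2 in turn.

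Some features with large differences were listed at 0 in a whole group. The precursor gene of the microRNA miR168, MIR168A, was listed at 0 in the 3 Col-0 libraries and at 73.4 and 95 FPKM in the GFP-GrxS5 libraries. The noncoding RNA AT1G55525 was listed at 0 in Col-0 and at 10.3 and 4.43 FPKM in GFP-GrxS5. The small nucleolar RNA AT1G75166 (296, 179 and 156 FPKM in Col-0 replicates 1 to 3), AT3G26539 (102, 60.4 and 53.8), AT2G11891 (12.5, 14.7 and 26.5) and the pseudogene RSU1 (20.9, 12.2 and 11) were each listed at 0 in both GFP-GrxS5 libraries. AT5G26620 had 4.65, 5.42 and 0 FPKM in Col-0 and 38.1 and 55.5 in GFP-GrxS5, a call lost without either 1 of the GFP-GrxS5 replicates (limma, Benjamini-Hochberg adjusted p from 0.0893 to 0.118, and 0.0026 to 0.124 over all alternatives). Its log2 change of 3.83 was 2.97 without Col-0 replicate 3. All of these except AT1G55525 span under 300 bp, as did 9 of the 1394 called genes. The FPKM of 1 fragment was estimated on longer genes and does not carry over to such lengths. High values here, such as those of MIR168A, may therefore rest on few fragments.

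GrxS5 was the one member past the threshold among the 6 tested GrxS1 to GrxS8 genes. GrxS3 had 4.02 ± 2.17 FPKM in Col-0 and 7.27 ± 2.43 in GFP-GrxS5, GrxS4 6.58 ± 2.34 and 3.22 ± 0.584, and GrxS6 56.2 ± 12.5 and 40.3 ± 0.331 (SD, n = 3 and n = 2; limma, Benjamini-Hochberg adjusted p = 0.28, 0.128 and 0.18). GrxS6 passed without Col-0 replicate 3 and with the replicate block (limma, Benjamini-Hochberg adjusted p = 0.0218 and 0.0384, in a range of 0.0218 to 0.354 over all alternatives). GrxS7 had 3.11 ± 1.89 and 3.24 ± 2.3 FPKM and GrxS8 3.34 ± 0.526 and 2.55 ± 2.64 (limma, Benjamini-Hochberg adjusted p = 0.981 and 0.531), with signs that changed between alternatives. GrxS1 and GrxS2 stayed below the expression filter. The family list did not pass (camera, Benjamini-Hochberg adjusted p = 0.782, direction up), with a median of -0.21, a mean of 0.62 and 1 member past the threshold adjusted over the list alone. GrxS3, GrxS4, GrxS5, GrxS7 and GrxS8 lie side by side on chromosome 4 with similar sequences, so their shares of the reads are uncertain.

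CEP-CEPD signalling is the peptide pathway that signals nitrogen demand between root and shoot. Its glutaredoxin gene CEPD1 rose from 16.6 ± 0.973 to 29.2 ± 7.47 FPKM (SD, n = 3 and n = 2). That call was lost without any 1 of the Col-0 replicates or GFP-GrxS5 replicate 2 (limma, Benjamini-Hochberg adjusted p from 0.0738 to 0.114, and 0.019 to 0.114 over all alternatives). CEPH, a phosphatase that acts on nitrate uptake, had 58.6 ± 11.3 and 37 ± 11.4 FPKM, and the transcription factor genes TGA1 and TGA4 had 247 ± 12.3 and 220.5 ± 0.768, and 53.6 ± 0.44 and 44.9 ± 6.41 (limma, Benjamini-Hochberg adjusted p = 0.103, 0.208 and 0.171). The 9 tested members did not pass as a set (camera, Benjamini-Hochberg adjusted p = 0.269), with a median of -0.26 and 1 past the threshold adjusted over the list alone.

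Of 20 nitrogen assimilation genes, 8 fell, 2 rose and 10 did not pass (11 fell and 3 rose adjusted over the list alone). Their median log2 change was -0.38 (camera, Benjamini-Hochberg adjusted p = 3.87e-04; adjusted p = 0.569 with an estimated correlation). NIA1 (AT1G77760) fell by 0.95 (SE 0.11) on the log2 scale, and the nitrite reductase gene NIR1 fell from 357 ± 42.3 to 196 ± 2.27 FPKM (SD, n = 3 and n = 2; limma, Benjamini-Hochberg adjusted p = 0.00422 and 0.0042). NIA2, another nitrate reductase gene, had 182 ± 30.8 and 131 ± 6.64 FPKM and did not pass (limma, Benjamini-Hochberg adjusted p = 0.0844). G6PD3 and RFNR2, plastid enzymes that supply reductant, fell from 84 ± 11.7 to 42.4 ± 2.67 and from 518 ± 83.8 to 285 ± 24.7 FPKM (limma, Benjamini-Hochberg adjusted p = 0.00512 and 0.0111). The RFNR2 call was lost without GFP-GrxS5 replicate 2 (limma, Benjamini-Hochberg adjusted p = 0.0662, and 0.0082 to 0.0662 over all alternatives). The asparagine synthetase gene ASN1 rose from 40.7 ± 7.36 to 81.2 ± 19.3 FPKM and the glutamate dehydrogenase gene GDH2 from 104 ± 3.48 to 157 ± 27.8. ASN1 lost its call without Col-0 replicate 2 or GFP-GrxS5 replicate 1 (limma, Benjamini-Hochberg adjusted p from 0.054 to 0.11, and 0.0194 to 0.11 over all alternatives). GDH2 lost its call without any 1 of the Col-0 replicates or GFP-GrxS5 replicate 1 (limma, Benjamini-Hochberg adjusted p from 0.0568 to 0.0731, and 0.0118 to 0.0906 over all alternatives). In the same libraries the shoot photosynthesis markers had a median log2 change of 0.89.

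Nitrate transport genes went both ways: of 15 tested, 6 fell, 1 rose and 8 did not pass (8 fell and 4 rose adjusted over the list alone). NRT1.5 (AT1G32450; chromosome 1, 11715150 to 11719970) fell by 1.32 (SE 0.10) on the log2 scale and NRT2.6 from 35.2 ± 3.36 to 14.7 ± 2.08 FPKM (SD, n = 3 and n = 2; limma, Benjamini-Hochberg adjusted p = 9.56e-04 and 0.00298). The high-affinity transporter gene NRT2.1, near-identical to NRT2.2, fell from 731 ± 130.2 to 441 ± 64.2 FPKM, and its partner NRT3.1 from 554 ± 108 to 349 ± 30.2 (limma, Benjamini-Hochberg adjusted p = 0.0317 and 0.0442). NRT2.1 lost its call without Col-0 replicate 2 or either 1 of the GFP-GrxS5 replicates (limma, Benjamini-Hochberg adjusted p from 0.0564 to 0.143, and 0.0254 to 0.143 over all alternatives). NRT3.1 lost its call without Col-0 replicate 2 or either 1 of the GFP-GrxS5 replicates (limma, Benjamini-Hochberg adjusted p from 0.0762 to 0.176, and 0.0361 to 0.176 over all alternatives). The nitrate transceptor gene NRT1.1 fell from 127 ± 22.5 to 73.5 ± 16.3 FPKM, a call lost without any 1 of the Col-0 replicates or GFP-GrxS5 replicate 2 (limma, Benjamini-Hochberg adjusted p from 0.0577 to 0.158, and 0.0279 to 0.158 over all alternatives). The anion channel gene SLAH1 fell from 2.91 ± 1.01 to 0.23 ± 0.326 FPKM, a call lost without Col-0 replicates 2 or 3 or either 1 of the GFP-GrxS5 replicates (limma, Benjamini-Hochberg adjusted p from 0.0564 to 0.106, and 0.0193 to 0.106 over all alternatives). CLCa, which moves nitrate into the vacuole, rose from 41.7 ± 1.79 to 69.8 ± 12.7 FPKM, a call lost without GFP-GrxS5 replicate 1 (limma, Benjamini-Hochberg adjusted p = 0.0573, and 0.0111 to 0.0617 over all alternatives). Among 5 ammonium transport genes AMT1;1 fell from 170.5 ± 11.8 to 117 ± 21.3 FPKM, and 3 members fell adjusted over the list alone. The AMT1;1 call was lost without any 1 of the Col-0 replicates or GFP-GrxS5 replicate 2 (limma, Benjamini-Hochberg adjusted p from 0.0734 to 0.118, and 0.0216 to 0.118 over all alternatives).

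As sets, nitrate and ammonium transport had medians of -0.48 and -0.48 (camera, Benjamini-Hochberg adjusted p = 0.0394 and 0.0349; adjusted p = 0.637 for both with an estimated correlation), beside a photosynthesis marker median of 0.89. Both set calls were lost without a variance trend (camera, Benjamini-Hochberg adjusted p = 0.0598 for both) and under quantile normalization (0.0642 and 0.0517). Both were also lost without GFP-GrxS5 replicate 2 (camera, Benjamini-Hochberg adjusted p = 0.169 and 0.179), and that for nitrate without Col-0 replicate 3 (0.0504). Over all alternatives adjusted p (Benjamini-Hochberg) ran from 0.0141 to 0.637 for nitrate and from 0.0030 to 0.637 for ammonium. Among 16 nitrogen response regulators the repressor genes HHO1 and LBD37 fell, from 38.8 ± 2.03 to 23.63 ± 0.128 and from 97.1 ± 2.69 to 76.7 ± 4.21 FPKM (SD, n = 3 and n = 2; limma, Benjamini-Hochberg adjusted p = 0.0063 and 0.0373). The LBD37 call was lost without any 1 of the Col-0 replicates or either 1 of the GFP-GrxS5 replicates (limma, Benjamini-Hochberg adjusted p from 0.0773 to 0.148, and 0.0239 to 0.148 over all alternatives). The regulators did not pass as a set (camera, Benjamini-Hochberg adjusted p = 0.51; median 0.21), with 2 higher and 3 lower adjusted over the list alone.

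Iron deficiency genes were lower in GFP-GrxS5 roots. Of 30 members 20 fell, 2 rose and 8 did not pass (21 fell and 2 rose adjusted over the list alone). Their median log2 change was -1.002 (camera, Benjamini-Hochberg adjusted p = 4.77e-15; adjusted p = 0.261 with an estimated correlation). FRO2 (AT1G01580; chromosome 1, 209395 to 213041) fell by 2.13 (SE 0.19) and IRT1 (AT4G19690; chromosome 4, 10707426 to 10709015) by 1.78 (SE 0.19) on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.00142 and 0.00314). Among the transcription factor genes of the list bHLH38 fell from 27.7 ± 1.69 to 7.14 ± 1.03 FPKM, MYB72 from 18.3 ± 2.78 to 2.87 ± 0.869 and FIT from 82 ± 8.18 to 47.9 ± 2.93 (SD, n = 3 and n = 2; limma, Benjamini-Hochberg adjusted p = 6.45e-04, 0.00117 and 0.00738). The coumarin synthesis genes F6'H1 and S8H fell from 207 ± 15.5 to 75.8 ± 23.5 and from 125 ± 22.7 to 27.9 ± 12.9 FPKM, and the coumarin exporter gene PDR9 from 119 ± 4.65 to 55.5 ± 6.19 (limma, Benjamini-Hochberg adjusted p = 0.00421, 0.00467 and 0.00116). The nicotianamine synthase gene NAS1 fell from 233 ± 22 to 88.8 ± 16 FPKM (limma, Benjamini-Hochberg adjusted p = 0.00169). The members that rose were the metal transporter gene NRAMP1, from 31.5 ± 0.853 to 42.8 ± 3.53 FPKM, and ZIF1, from 17.9 ± 1.26 to 25.9 ± 0.127. NRAMP1 lost its call without any 1 of the Col-0 replicates or either 1 of the GFP-GrxS5 replicates (limma, Benjamini-Hochberg adjusted p from 0.0669 to 0.147, and 0.0278 to 0.147 over all alternatives). ZIF1 lost its call without Col-0 replicates 1 or 2 or either 1 of the GFP-GrxS5 replicates (limma, Benjamini-Hochberg adjusted p from 0.0841 to 0.114, and 0.022 to 0.114 over all alternatives). The shoot photosynthesis markers of the same libraries had a median of 0.89.

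Of 11 copper deficiency genes 5 fell, 0 rose and 6 did not pass (6 fell and 1 rose adjusted over the list alone). Their median log2 change was -0.65 (camera, Benjamini-Hochberg adjusted p = 5.50e-05; adjusted p = 0.261 with an estimated correlation), beside a median of 0.89 for the shoot photosynthesis markers. COPT2 (AT3G46900; chromosome 3, 17268875 to 17269510) fell by 2.202 (SE 0.18) and FRO5 by 2.25 (SE 0.12) on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.00113 and 3.41e-04). The iron superoxide dismutase gene FSD1 fell from 556 ± 14.8 to 257 ± 27.6 FPKM (SD, n = 3 and n = 2; limma, Benjamini-Hochberg adjusted p = 7.79e-04). YSL2 and ZIP2 fell from 19.3 ± 1.74 to 11.3 ± 0.0838 and from 59.9 ± 10.1 to 37.6 ± 0.00255 FPKM. YSL2 lost its call without either 1 of the GFP-GrxS5 replicates (limma, Benjamini-Hochberg adjusted p from 0.0672 to 0.0676, and 0.0102 to 0.0676 over all alternatives). ZIP2 lost its call without Col-0 replicate 2 or either 1 of the GFP-GrxS5 replicates (limma, Benjamini-Hochberg adjusted p from 0.0633 to 0.115, and 0.0227 to 0.115 over all alternatives).

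Of 15 sulfur deficiency genes 3 fell and 0 rose (7 and 0 adjusted over the list alone). Their median was -0.28 (camera, Benjamini-Hochberg adjusted p = 3.87e-04; adjusted p = 0.261 with an estimated correlation), in the libraries where the shoot photosynthesis markers had a median of 0.89. The sulfate reduction genes APR1 and APR2 fell from 102 ± 15.4 to 54.4 ± 7.1 and from 56.4 ± 5.15 to 37.2 ± 2.19 FPKM, and the sulfate transporter gene SULTR2;1 from 14.8 ± 1.35 to 8.22 ± 1.71 (SD, n = 3 and n = 2). APR1 lost its call without GFP-GrxS5 replicate 2 (limma, Benjamini-Hochberg adjusted p = 0.0661, and 0.00756 to 0.0661 over all alternatives). APR2 lost its call without Col-0 replicate 2 or either 1 of the GFP-GrxS5 replicates (limma, Benjamini-Hochberg adjusted p from 0.0525 to 0.0874, and 0.0138 to 0.0874 over all alternatives). SULTR2;1 lost its call without any 1 of the Col-0 replicates or GFP-GrxS5 replicate 2 (limma, Benjamini-Hochberg adjusted p from 0.0653 to 0.114, and 0.0219 to 0.114 over all alternatives). The 16 tested phosphate starvation genes did not pass (camera, Benjamini-Hochberg adjusted p = 0.691, direction down), with a median of 0.03 and a mean of -0.07. Adjusted over the list alone 0 of them passed limma's test, and 2 were higher and 2 lower at an unadjusted p under 0.05.

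Nuclear photosynthesis genes rose in GFP-GrxS5 roots. Of 25 tested markers 22 rose and 0 fell (25 and 0 adjusted over the list alone), with a median log2 change of 0.89 (camera, Benjamini-Hochberg adjusted p = 1.68e-21; adjusted p = 0.261 with an estimated correlation). RBCS1A (AT1G67090; chromosome 1, 25048158 to 25049424) rose by 1.22 (SE 0.08) and LHCB1.3 (AT1G29930; chromosome 1, 10478005 to 10479048) by 1.43 (SE 0.12) on the log2 scale, RBCS3B from 10.3 ± 0.964 to 37.8 ± 3.13 FPKM and the Calvin cycle gene GAPA from 27.2 ± 1.44 to 60.2 ± 7.18 (SD, n = 3 and n = 2; limma, Benjamini-Hochberg adjusted p = 6.15e-04, 0.0014, 6.45e-04 and 0.00192). RBCS and LHCB1 genes have near-identical copies, so the shares of single copies are uncertain.

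**Figure D3:**
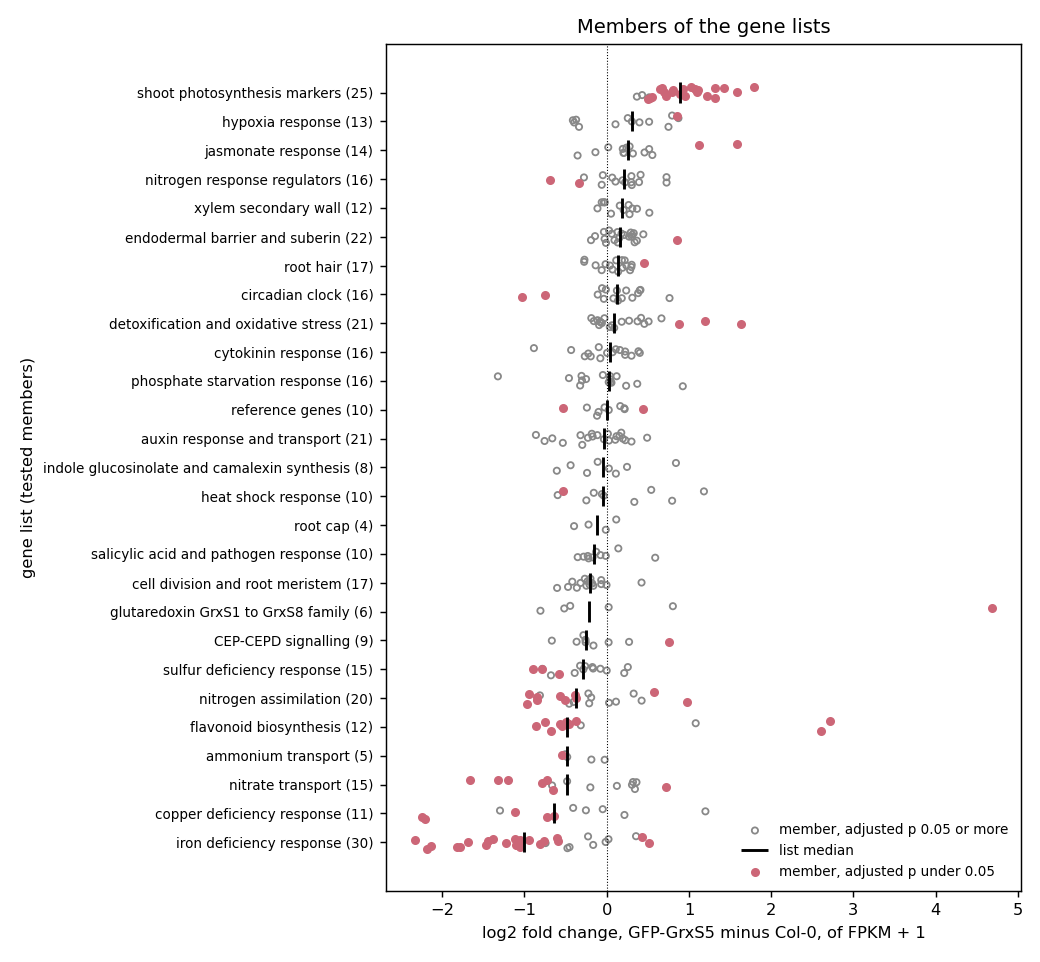
Log2 fold change (GFP-GrxS5 minus Col-0, of FPKM + 1) of each tested member of the 27 gene lists, sorted by list median (black bars), with filled red points for members past the adjusted p threshold and open grey points for the rest. The photosynthesis markers have the highest median (0.89) and the iron deficiency genes the lowest (-1.002).

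Flavonoid genes moved in both directions. Of 12 tested members 8 fell and 2 rose (8 and 3 adjusted over the list alone). The list's median was -0.48 while its mean was 0.12 (camera, direction down, Benjamini-Hochberg adjusted p = 0.00251; adjusted p = 0.615 with an estimated correlation), beside a photosynthesis marker median of 0.89. The flavonol synthase gene FLS1 fell from 195 ± 6.51 to 116 ± 5.55 FPKM, CHIL from 244 ± 3.01 to 167 ± 9.65 and the chalcone synthase gene CHS from 603 ± 28.4 to 439 ± 53.2 (SD, n = 3 and n = 2; limma, Benjamini-Hochberg adjusted p = 0.00197, 0.00495 and 0.0261). DFR, which acts in the anthocyanin branch with LDOX, rose from 3.12 ± 1.52 to 23.7 ± 7.69 FPKM (limma, Benjamini-Hochberg adjusted p = 0.00454). CHS lost its call without any 1 of the Col-0 replicates or GFP-GrxS5 replicate 2 (limma, Benjamini-Hochberg adjusted p from 0.0508 to 0.0951, and 0.021 to 0.156 over all alternatives).

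Of 14 jasmonate response genes 2 rose and 0 fell (2 and 0 adjusted over the list alone). Their median was 0.26 (camera, Benjamini-Hochberg adjusted p = 0.0243; adjusted p = 0.446 with an estimated correlation), beside a photosynthesis marker median of 0.89. The set call was lost without Col-0 replicate 1 or GFP-GrxS5 replicate 2 (camera, Benjamini-Hochberg adjusted p = 0.0686 and 0.0606, in a range of 0.00313 to 0.446 over all alternatives). The storage protein gene VSP2 rose from 125 ± 7.27 to 275 ± 30.4 FPKM (SD, n = 3 and n = 2) and the transcription factor gene ORA59 from 2.9 ± 1.22 to 10.4 ± 1.74. ORA59 lost its call without Col-0 replicate 1 or either 1 of the GFP-GrxS5 replicates (limma, Benjamini-Hochberg adjusted p from 0.0522 to 0.102, and 0.0136 to 0.102 over all alternatives).

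The catalase gene CAT3 rose from 364 ± 18.6 to 669 ± 5.34 FPKM and the hypoxia regulator HRE1 from 25.5 ± 2.37 to 46.9 ± 2.9 (SD, n = 3 and n = 2; limma, Benjamini-Hochberg adjusted p = 9.73e-04 and 0.00537). The neighbouring glutathione transferase genes GSTF6 and GSTF7 rose from 12 ± 4.36 to 39.4 ± 14.7 and from 15.5 ± 5.76 to 35.3 ± 3.87 FPKM. GSTF6 lost its call without Col-0 replicates 1 or 2 or GFP-GrxS5 replicate 1 (limma, Benjamini-Hochberg adjusted p from 0.0582 to 0.101, and 0.0131 to 0.101 over all alternatives). GSTF7 lost its call without Col-0 replicate 2 or either 1 of the GFP-GrxS5 replicates (limma, Benjamini-Hochberg adjusted p from 0.0962 to 0.162, and 0.0167 to 0.162 over all alternatives). Detoxification (21 genes, median 0.09) and hypoxia (13 genes, median 0.31) did not pass as sets (camera, Benjamini-Hochberg adjusted p = 0.121 and 0.119), with 3 and 1 members higher adjusted over the list alone. Without Col-0 replicate 3 both passed (camera, Benjamini-Hochberg adjusted p = 0.00491 and 0.00716), and hypoxia also without GFP-GrxS5 replicate 2 (0.0213). Over all alternatives adjusted p (Benjamini-Hochberg) ran from 0.00313 to 0.722 and from 0.00625 to 0.766.

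The clock genes GI and LNK1 fell from 16.7 ± 2.63 to 7.62 ± 0.962 and from 13 ± 1.37 to 7.29 ± 0.595 FPKM, and the heat shock protein gene HSP70-4 from 37.3 ± 2.82 to 25.4 ± 0.862 (SD, n = 3 and n = 2). GI lost its call without GFP-GrxS5 replicate 1 (limma, Benjamini-Hochberg adjusted p = 0.0738, and 0.00965 to 0.0738 over all alternatives). LNK1 lost its call without Col-0 replicates 1 or 2 or either 1 of the GFP-GrxS5 replicates (limma, Benjamini-Hochberg adjusted p from 0.0693 to 0.104, and 0.0186 to 0.104 over all alternatives). HSP70-4 lost its call without Col-0 replicates 2 or 3 or either 1 of the GFP-GrxS5 replicates (limma, Benjamini-Hochberg adjusted p from 0.0648 to 0.0957, and 0.0168 to 0.0957 over all alternatives). As sets the clock, heat shock, salicylic acid and pathogen, cytokinin, auxin, and indole glucosinolate and camalexin lists did not pass (camera, Benjamini-Hochberg adjusted p = 0.546, 0.782, 0.367, 0.782, 0.353 and 0.668). Their medians were 0.13, -0.05, -0.15, 0.04, -0.03 and -0.04. The heat shock mean was 0.12, and the cytokinin mean was -0.02 with a test direction of down. Adjusted over the list alone, 2 clock genes were higher and 2 lower, 1 heat shock gene was higher and 1 lower, and 1 indole glucosinolate or camalexin gene was higher and 2 lower. In the salicylic acid, cytokinin and auxin lists 0 genes passed limma's test adjusted over the list alone, and 1, 3 and 7 had an unadjusted p under 0.05.

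The 17 cell division and meristem genes were lower as a set, at a median of -0.21 (camera, Benjamini-Hochberg adjusted p = 3.28e-04; adjusted p = 0.261 with an estimated correlation), and the shoot photosynthesis markers of these libraries had a median of 0.89. Of its members 0 passed limma's test over all genes and 2 adjusted over the list alone, and 6 were lower and 0 higher at an unadjusted p under 0.05. The replication gene MCM2 had 22.7 ± 1.31 and 16.7 ± 0.581 FPKM and the stem cell regulator gene PLT1 9.43 ± 1.08 and 5.84 ± 0.0493 (SD, n = 3 and n = 2; limma, Benjamini-Hochberg adjusted p = 0.0549 and 0.0564). Both passed under quantile normalization (limma, Benjamini-Hochberg adjusted p = 0.0423 and 0.0433, in ranges of 0.042 to 0.173 and 0.0433 to 0.165 over all alternatives). PLT1 passed under no other alternative. MCM2 also passed with a filter of 5 FPKM, median-of-ratios scaling, nuclear genes at equal sums and robust moderation (limma, Benjamini-Hochberg adjusted p = 0.042, 0.0491, 0.0466 and 0.0498).

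The 22 endodermal barrier and suberin genes had a median of 0.17 (camera, Benjamini-Hochberg adjusted p = 0.0268; adjusted p = 0.69 with an estimated correlation), beside a photosynthesis marker median of 0.89. That call was lost without Col-0 replicate 1 or GFP-GrxS5 replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.18 and 0.371, in a range of 0.00194 to 0.69 over all alternatives). Its member CASP5, of the Casparian strip, rose from 3.76 ± 0.50 to 7.65 ± 1.13 FPKM (SD, n = 3 and n = 2) and was 1 of 22 past the threshold adjusted over the list alone. CASP5 lost its call without any 1 of the Col-0 replicates or either 1 of the GFP-GrxS5 replicates (limma, Benjamini-Hochberg adjusted p from 0.071 to 0.167, and 0.0303 to 0.167 over all alternatives). Root hair, xylem secondary wall and root cap markers had medians of 0.14, 0.18 and -0.12 and did not pass as sets (camera, Benjamini-Hochberg adjusted p = 0.33, 0.20 and 0.591). Adjusted over the list alone, 1 root hair, 0 xylem and 0 root cap genes passed limma's test, and 3, 2 and 0 had an unadjusted p under 0.05. The root hair gene PRP3 rose from 88.9 ± 7.25 to 123 ± 14.8 FPKM, a call lost under the scaling alternatives and without Col-0 replicates 1 or 2 or either 1 of the GFP-GrxS5 replicates (limma, Benjamini-Hochberg adjusted p from 0.0516 to 0.165, and 0.0358 to 0.165 over all alternatives).

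The 10 reference genes had a median of -2.60e-04 and a mean of 0.01 (camera, Benjamini-Hochberg adjusted p = 0.782), and adjusted over the list alone 2 were higher and 2 lower. The elongation factor gene EF1A fell from 2172 ± 86.3 to 1508 ± 105 FPKM (SD, n = 3 and n = 2). That call was lost without a variance trend and with the replicate block (limma, Benjamini-Hochberg adjusted p = 0.0602 and 0.156, in a range of 0.00146 to 0.156 over all alternatives). The ubiquitin gene UBQ10 rose from 1131 ± 26.2 to 1537 ± 163 FPKM, a call lost without any 1 of the Col-0 replicates or GFP-GrxS5 replicate 1 (limma, Benjamini-Hochberg adjusted p from 0.0697 to 0.0858, and 0.0107 to 0.188 over all alternatives).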

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

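The removal of short features and the GC and length correction were chosen only after the results were seen, and the other alternatives before. Of 78 named genes past the threshold, 46 stayed past it under every alternative that tested them and 0 changed sign. Each called gene had both GFP-GrxS5 libraries on the same side of all Col-0 libraries. Its sign could therefore change only under the alternatives that rescale or correct the values. Of 11 called lists, 7 stayed past the threshold in every camera fit with the preset correlation. The cause of the changes below was not tested, except that leaving out a library or fitting the block leaves fewer degrees of freedom. Higher and lower genes numbered 932 and 462, against 398 and 184 without a variance trend, 418 and 176 with the replicate block, and 313 to 594 and 192 to 242 without 1 library; at least 2-fold higher genes numbered 230, against 125 to 229 without 1 library. Only 2 replicate numbers are shared, and deviations from the group means of same-numbered libraries correlated at -0.039 and -0.0080. The deviations of the 2 GFP-GrxS5 libraries mirror each other, so this check cannot exclude a shared batch. The labels do not say that a number marks a shared day. With the replicate block, adjusted p (limma's camera, Benjamini-Hochberg) was 0.0522 for nitrate and 0.0522 for ammonium transport (both lost), 0.00313 for detoxification and 0.00625 for hypoxia (both gained), and in the other direction, past no threshold, 0.853 for the GrxS family, 0.969 for indole glucosinolates and 0.913 for reference genes. The nitrate call was also lost with a filter of 5 FPKM (0.114), quantile normalization (0.0642), no trend (0.0598) and the GC and length correction (0.0928), and the ammonium call with quantile normalization (0.0517) and no trend (0.0598). With an estimated correlation, photosynthesis, iron, copper, sulfur and cell division had adjusted p = 0.261, nitrate and ammonium 0.637, nitrogen assimilation 0.569, flavonoids 0.615, jasmonate 0.446 and suberin 0.69, all lost. With fry the calls for nitrate (0.156), ammonium and suberin (0.275), nitrogen assimilation and jasmonate (0.0745) and flavonoids (0.0974) were lost, xylem was gained (0.0444) and cytokinin, past no threshold, changed direction (0.907), as did phosphate with a filter of 5 FPKM (0.946). Without 1 library, adjusted p ran from 0.0141 to 0.169 for nitrate, 0.0030 to 0.179 for ammonium, 0.00967 to 0.0686 for jasmonate, 0.00194 to 0.371 for suberin, 0.00491 to 0.324 for detoxification and 0.00716 to 0.60 for hypoxia, with calls lost or gained, and from 0.333 to 0.857 for the GrxS family, 0.443 to 0.926 for phosphate and 0.151 to 0.857 for the clock, whose directions changed past no threshold. GrxS7, past no threshold, had a log2 change of -0.0017 under quantile normalization, -0.24 with the block, -0.0927 after the GC and length correction and -0.56 to 0.61 without 1 library, against 0.02 in the main result; GrxS8 had -1.36 to 0.33 without 1 library. At these depths genes near 1 FPKM rest on few fragments. The simulation recovered 22.4% of 1.5-fold changes. It gave 167 calls against 1394 in the data, so its cut on unadjusted p was stricter and that share does not carry over.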

Other observations

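The tests on the leaf marker median and on GC content and length were set down before their results were seen; all other tests here, the 4 added lists and the GC and length correction itself were chosen only after the main results were seen. Genes of aliphatic glucosinolate synthesis, the methionine-derived defence compounds of Brassicaceae, fell in GFP-GrxS5 roots. Of 18 tested members 16 fell and 0 rose, among them BCAT4, of chain elongation, from 229 ± 6.51 to 101 ± 2.89 FPKM and CYP83A1, of the core pathway, from 130.3 ± 6.42 to 55.1 ± 4.55 (SD, n = 3 and n = 2; limma, Benjamini-Hochberg adjusted p = 3.41e-04 and 6.45e-04). The list was written after 5 of its members had been seen to fall, and testing its other members apart was decided after all values were known. The other 13 tested members, of which 11 fell, had a median log2 change of -0.78, beside a median of 0.89 for the shoot photosynthesis markers. Over the 4 added lists their adjusted p was 9.90e-15, and 0.0474 with an estimated correlation (camera, Benjamini-Hochberg). The planned lists were adjusted over 27 lists, so 0.0474 cannot be set against their values with an estimated correlation. The indole glucosinolate and camalexin list had a median of -0.04, and the difference between the lists was not tested.

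Genes of carbon starvation and dormancy were higher. Of 12 tested members 7 rose and 0 fell, with the dormancy-associated genes DRM1 and DRM2 rising from 191 ± 31.7 to 555 ± 20.7 and from 162 ± 19.6 to 918 ± 139.9 FPKM (SD, n = 3 and n = 2; limma, Benjamini-Hochberg adjusted p = 0.00142 and 2.85e-04). This list was written after 2 members, DRM2 and EXL2, had been seen to rise. The other 10, of which 5 rose, had a median of 0.84 (camera, Benjamini-Hochberg adjusted p = 1.77e-06; adjusted p = 0.303 with an estimated correlation), so that the call rests on the preset correlation. In the same libraries the shoot photosynthesis markers had a median of 0.89. The 2 tested chloroplast development regulators, GLK2 and HY5, did not pass (camera, Benjamini-Hochberg adjusted p = 0.859).

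Of 18 leaf markers outside photosynthesis 6 were tested, and as a set they did not rise with the photosynthesis markers. Their median was -0.253 (camera, Benjamini-Hochberg adjusted p = 0.103) against 0.445, which is 0.5 times the photosynthesis median. The 95% bootstrap interval of -0.525 to 0.0395 resamples genes, so it does not measure the spread between libraries. Of the 6 genes, 5 had a Col-0 mean above 1 FPKM, so a small share of leaf would move them little. Transcripts abundant in leaves also stayed near 0. Among TGG1, TGG2, ESM1 and CA1 the highest gain in mean FPKM was 0.466, and none was above 0.836 FPKM in any library. The tested photosynthesis markers gained a median of 23.3 and RBCS1A 214. CA1 is itself on the photosynthesis marker list, where it stayed below the expression filter. TGG1, TGG2 and ESM1 are untested members of the leaf marker list. After the GC and length correction the photosynthesis median was 0.833, which with the leaf transcripts argues against these biases and leaf tissue as the whole source, though no leaf library was analysed here. A library batch that coincides with the genotype and a difference of the GFP-GrxS5 roots themselves, such as their exposure to light, stay open.

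The fall of the iron deficiency genes kept a median of -0.987 after the GC and length correction, and its median nearest to 0 without any 1 library was -0.897, which argues against those biases and against a single library as the source. A lower share of hair cells would lower root hair genes too, and their median was 0.14 (camera, Benjamini-Hochberg adjusted p = 0.33). The 95% bootstrap interval of -0.0135 to 0.24 also resamples genes and not libraries. Markers of the epidermis outside hair cells were not tested, so a lower share of those cells stays open. The genotype itself and a batch or growth difference that coincides with it were not tested apart and stay open.

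Short features whose FPKM rests on few fragments were tested for next. The 5 features listed at 0 in one genotype and above 5 FPKM in every library of the other (4 at 0 in GFP-GrxS5, 1 in Col-0) all span under 300 bp, 100% against 0.432% of the tested features. AT1G55525, at 0 in Col-0 and at 10.3 and 4.43 FPKM in GFP-GrxS5, spans 417 bp. It missed the limit of 5 FPKM, which was set after the data were seen. The values of the 5 short features may come from few fragments or from how the authors' processing or a library kit treats short RNAs. The test used locus length only. Over Col-0 replicates 1 to 3, AT1G75166 (296, 179 and 156 FPKM), AT3G26539 (102, 60.4 and 53.8) and RSU1 (20.9, 12.2 and 11) kept near the same proportions. AT2G11891 (12.5, 14.7 and 26.5) did not. The same few fragments in each would give such shared proportions, but fragments at these lengths were not counted. A genotype difference is not excluded for any of the 5 features.

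The 10 splits of the 5 libraries into 3 and 2 are too few for a share under 0.05: 1 of the 10, the real one, gave 1394 genes, and the highest of the others gave 8 (limma, Benjamini-Hochberg).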
